A study of Mus musculus with 276 samples.

How the data were processed

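Total RNA of cultures of mouse Epiblast Stem Cells was hybridized to MouseWG-6 v2 BeadArrays and read on an iScan, per the labels and the series design text. The authors deposited a raw table with the signal intensity of each probe on each array, and beside it a detection p-value, per the file headers. Its detection p-values rise in even steps, 936 on the first array, and were read as ranks among negative controls, judged from these steps. The software that wrote this table, and any background subtraction in it, are not given in the sources used here. The authors also deposited a value table on a log2 scale, made by variance stabilization and robust spline normalization with lumi, per the series design text, which gives no version. The log2 scale was checked against the raw signal: the median r per array was 0.984 (lowest 0.964), the slope for bright probes 1.01, and every column fitted best the raw column of their own array. Line, morphogen, compound, dose and batch were taken from the labels. The labels carry no replicate numbers, so replicates are numbered in the order of the samples within a group, and their order has no meaning.

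The table has 45281 probes, of which 34885 carry 1 gene symbol, 18 several and 10378 none. Probes with several symbols or none were not used here. Of the probes with 1 symbol, 34807 had a matching gene number in the reference, and no symbol needed an update. Raw signal was normalized with neqc of limma 3.58.1 in R 4.3.3 (normexp background correction from the detection p-values, quantile normalization, offset 16) over all arrays together. A probe was kept where its detection p was under 0.01 on at least 8 arrays, which 18395 probes with a symbol met. The probe with the highest mean stood for each gene, which left 11527 genes. Signal over background differed between arrays: the 95th percentile of the raw signal was 4.46 to 21.0 times the background (median 12.5). The number of arrays limits the precision.

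Linear models were fitted with limma, each with the slide as a random block (duplicateCorrelation with statmod 1.5.0) and eBayes with trend and robust settings. The factorial model (batch 100, 32 slides, 164 residual degrees of freedom, slide correlation 0.188) had a mean for each line and condition and additive terms for the compounds. The SB431542 panel model (84 arrays, 14 slides, 44 residual degrees of freedom, slide correlation 0.169) had a mean for each condition and compound and a batch term. Adjusted p-values are Benjamini-Hochberg values from limma over all genes of a comparison. The means and SDs of groups printed beside them are over arrays with any compound. Gene lists were tested with cameraPR at a preset correlation of 0.01, adjusted over the 32 lists of a comparison, and again with the correlation estimated from the residuals. List means and their 95% intervals come from lmFit on the list averages. Dorsomorphin with BMP4 was tested by 1 added term. Profiles of shared compounds were compared by 100000 permutations of the compound names.

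The comparisons, the lists, the thresholds and the rule for named genes were fixed before the data were examined. For each condition and for the lines, the rule names the 10 genes with the highest and the 10 with the lowest change among those that passed, Riken and other provisional names left out, and the measured members of lists that fit the treatment. For interactions and pairs of compounds it names the 5 highest and 5 lowest. For the 8 and the 5 compounds with the most genes changed in the SB431542 and the factorial panel it names the 3 highest and 3 lowest, with the largest changes among the target list of each compound that has one. For compounds with 5 or fewer changed genes all of these may also be named, which the rule did not foresee. Probes without a symbol were not analysed here.

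The fits were tested on simulated data with known changes in the 11527 genes. Of genes given a log2 change of 0.8, limma recovered 98.5% for BMP4, 97.0% for SB431542 in EpiSC-5, 83.6% for the line-dependent response to retinoic acid, 94.0% for the lines in CMAF and 88.1% for SB431542 in EpiSC-G. It recovered 61.2% for rapamycin in the SB431542 panel, 82.1% in the factorial panel and 56.7% for LDN-193189 against dorsomorphin. False calls numbered 0 to 6. The simulated arrays had normal errors, a shared slide term and no mixed labels, so these numbers hold for that setting alone. On the real arrays, shuffled line labels called up to 2752 genes for the line-dependent response to PD0325901. A simulated interaction of -1 over the 10 BMP targets came back as -1.14. The permutation test gave p = 1e-05, the smallest it can give, with shared simulated effects and p = 0.704 without.

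Alternatives tried were the authors' value table, no background correction, no detection filter and a stricter one, no slide block, the slide as a fixed block, the second-brightest probe, a 2-fold minimum, each line or batch alone, other controls, arrays without compound, and leaving out arrays. In the factorial panel the arrays of each compound, or of no compound, were left out in turn, and in the SB431542 panel each array. These refits, and those of single lines or batches, keep the slide correlation of the full fit. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.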

Results

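Epiblast stem cells (EpiSC) are pluripotent lines derived from the mouse postimplantation epiblast and kept with FGF and Activin. RNA of 2 lines, EpiSC-G and EpiSC-5, was measured on Illumina MouseWG-6 v2 arrays, set on 46 slides of 6. Cells stayed in CMAF (conditioned medium with bFGF and Activin) or were exposed for 24 hours to BMP4 (100 ng/ml), retinoic acid (5 µM), the MEK inhibitor PD0325901 (1 µM), the Activin and Nodal receptor inhibitor SB431542 (10 µM) or embryoid body culture. A further set of arrays is labelled with no morphogen. Most cultures also received a compound for 36 hours. The labels give 3 array batches. Batch 100 crossed both lines and the conditions with 15 compounds, and is called the factorial panel. In it, CMAF had 36 arrays, embryoid body 38, no morphogen 34, BMP4 26, retinoic acid 24, PD0325901 22 and SB431542 (EpiSC-5 alone) 12. Batches 80 and 81 (84 arrays, EpiSC-G alone) tested 36 compounds, by the labels, on top of SB431542, with 2 arrays per compound, and are called the SB431542 panel. The series text counts 33 compounds, and the sources used here do not explain the difference. Between 23.8% and 38.8% of probes were detected per array (median 33.0%). The number of arrays limits the precision of every value.

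A gene is said to have changed where the limma fit gave a Benjamini-Hochberg adjusted p under 0.05 and a change of at least 1.5-fold. Each value is a log2 change with its standard error, and condition effects in the factorial panel are means of both lines with compounds as additive terms. Nothing in the labels says that replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical. Almost all CMAF arrays of the factorial panel lay on slides without arrays of the BMP4, retinoic acid or PD0325901 condition. Effects of these 3 conditions are therefore hardly separated from slide differences. All conditions of the factorial panel share CMAF arrays, so genes and lists that recur among them are not independent results and may reflect CMAF itself. In all, 11527 genes were tested, and 32 gene lists fixed before the data were examined were tested with limma's cameraPR. Over the 15 comparisons, 122 of 480 list tests passed, and 53 passed with an estimated correlation. Where a probe was not well above background on any array of a group, only a bound is given, written "at least". It is the bright group's mean minus the dim group's mean of, per array, the higher of the lowest signal among detected probes and the probe's own value.

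BMP4 asks how the cells leave the epiblast state when this morphogen is added. It raised 1062 genes and lowered 729 against CMAF (26 and 36 arrays), in all 852 without background correction. Id1, an immediate target of BMP receptor signalling, rose most, by 6.54 ± 0.33 (adjusted p = 1.02e-42, limma), from a mean log2 signal of 6.15 ± 1.94 (SD, n = 36) to 12.4 ± 0.33 (SD, n = 26). It was detected on 14 of the 36 CMAF arrays. Of 10 measured BMP targets, 8 rose and 1 fell, with the same counts adjusted over the list alone. Id2 rose by 3.40 ± 0.18, Id3 by 3.44 ± 0.24, Smad6 by 1.59 ± 0.13 and Msx1 by 4.04 ± 0.30. Id4, below detection on all 36 CMAF arrays, was at least 1.41-fold higher (adjusted p = 9.99e-27, limma). Hey1, also a Notch target, fell by 1.51 ± 0.13, and Dlx5 stayed at -0.14 ± 0.09 (adjusted p = 0.215). The list mean was 2.67 (95% interval 2.41 to 2.93; adjusted p = 5.83e-14).

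Genes of surface ectoderm and trophoblast moved together under BMP4: 12 of 15 rose, 1 fell and 2 did not pass, also adjusted over the list alone. The transcription factors Gata3 (3.97 ± 0.21), Gata2 (3.97 ± 0.24), Tfap2a (4.35 ± 0.24) and Tfap2c (2.72 ± 0.27) rose. So did the keratins of simple epithelia Krt8 (3.44 ± 0.23), Krt18 (2.83 ± 0.20) and Krt19 (3.10 ± 0.17), as well as Wnt6 (3.39 ± 0.26) and Dlx3 (2.16 ± 0.21). Hand1 was detected on 11 of 26 BMP4 arrays and on 0 of 36 CMAF arrays, and Cdx2 rose by 0.90 ± 0.20. The placental cadherin Cdh3 fell by 1.15 ± 0.17. The list mean was 2.33 (95% interval 2.08 to 2.58; adjusted p = 4.45e-16), and the call held at adjusted p = 0.00121 with an estimated correlation. Among primitive streak and mesoderm genes, Wnt3 (1.34 ± 0.19) and Evx1 (1.76 ± 0.24) rose, while Mixl1 (-0.48 ± 0.20), Eomes (-0.53 ± 0.23) and Fgf8 (-0.21 ± 0.29) did not pass. Gsc, detected on 1 BMP4 and 5 CMAF arrays, fell by 0.62 ± 0.23, but its change was 0.24 on arrays without compound.

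Outside these programmes, the cytoskeletal and membrane genes Ahnak (4.89 ± 0.24), Anxa3 (4.61 ± 0.24), Lgals3 (4.59 ± 0.23) and Pmp22 (5.57 ± 0.32) were among the highest, with Meis2 (4.70 ± 0.32), Sct, Gbp2 and Vgll3. The lowest were Trh (-4.43 ± 0.44), Igfbp5, Fgf5 (-3.25 ± 0.29), Stc1, Ankrd37, Lefty1 (-2.80 ± 0.39), Fgf15, Pdk1, Rsph1 and Brinp2. Of 15 glycolysis and hypoxia genes, 12 fell and 1 rose (adjusted p = 5.83e-08; 0.0337 with an estimated correlation). Actin and SRF targets (8 of 14 rose), STAT3 targets (6 of 11 rose), p53 targets (7 of 15 rose, 1 fell) and imprinted genes (7 of 15 rose) passed with both correlations. Of 10 primed epiblast genes, which mark the postimplantation state, 6 fell and 1 rose (adjusted p = 0.00364; adjusted p = 0.0640 with an estimated correlation). With arrays without compound only, the count of changed genes was 819 in place of 1791, and 491 with the authors' value table.

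Retinoic acid patterns the posterior nervous system and body axis. It raised 1181 genes and lowered 847 (24 arrays). Its total was 974 without background correction and 535 with the authors' value table. Of 12 anterior Hox genes, 11 rose, and the 12th, Hoxa3, detected on 7 of 24 retinoic acid arrays and on 0 of 36 CMAF arrays, did not pass. Hoxa5, detected on 3 of 36 CMAF arrays, rose by 7.66 ± 0.42 (adjusted p = 5.93e-38, limma), Hoxb5 by 6.44 ± 0.37, Hoxb4 by 5.50 ± 0.31, Hoxb2 by 4.65 ± 0.30 and Hoxb1 by 2.84 ± 0.25. Hoxb5, Hoxb4 and Hoxb2 were detected on 2, 4 and 4 of the 36 CMAF arrays, some of which carry retinoic acid as the compound. The sizes of these Hox changes therefore rest on background signal in CMAF and are not exact. The list mean was 3.16 (95% interval 2.80 to 3.53; adjusted p = 2.03e-15; 0.0041 with an estimated correlation). Of 16 retinoic acid targets, 12 rose and none fell. Cyp26a1, which degrades retinoic acid, rose by 6.53 ± 0.46, the receptor gene Rarb by 4.40 ± 0.22, Stra6, a retinol transporter, by 3.13 ± 0.22 and the binding protein gene Crabp2 by 6.01 ± 0.34. Meis1 (4.40 ± 0.27), Meis2 (6.27 ± 0.32) and Tshz1 (5.22 ± 0.31) rose, and Rarg did not pass (-0.21 ± 0.16). Both counts were the same adjusted over the list alone.

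Primed epiblast genes fell as a list with retinoic acid. The forebrain regulator Otx2 fell by 4.22 ± 0.23, Nanog by 3.92 ± 0.28, Fgf5 by 3.47 ± 0.30 and Hopx by 3.29 ± 0.23, and Fgf15 was at -3.90 ± 0.28. Trh, Jakmip1, Vrtn, Bcl11b and Bcl11a completed the 10 lowest. Of 10 primed epiblast genes, 5 fell and 2 rose (adjusted p = 0.000157; 0.0186 with an estimated correlation). Core pluripotency genes (2 rose, 4 fell of 10) passed at adjusted p = 0.0243 and were lost at adjusted p = 0.0829 with an estimated correlation. Neuroectoderm genes did not move as a group: Gbx2, a hindbrain gene, rose by 5.07 ± 0.35, Msi1 by 0.64 ± 0.13 and Nes by 0.59 ± 0.15, and 9 of 12 did not pass. In EpiSC-G alone the Nes value was -0.17. The milk protein gene Csn3 (5.90 ± 0.26), Zfp703 (6.34 ± 0.33) and Pmp22 (5.51 ± 0.33) were among the highest.

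PD0325901 blocks MEK, which lies between FGF and ERK. It raised 1343 genes and lowered 1229 (22 arrays). Its total was 1201 without background correction and 666 with the authors' value table. Of 15 FGF and ERK targets, 8 fell, 3 rose and 4 did not pass, also adjusted over the list alone. Egr1 fell by 2.85 ± 0.21 (adjusted p = 1.15e-27, limma), Etv4 by 2.22 ± 0.19, Spry4 by 1.95 ± 0.16, Etv5 by 1.28 ± 0.18, Dusp6 by 1.11 ± 0.17 and Myc by 0.67 ± 0.14. Spred1 and Spred2, feedback inhibitors of the pathway, fell by 0.95 ± 0.13 and 0.96 ± 0.12. The members that rose were Phlda1 (3.03 ± 0.23), the ERK phosphatase gene Dusp5 (1.90 ± 0.17) and the immediate early gene Fos (1.14 ± 0.18). The list mean was -0.51 (95% interval -0.68 to -0.34), and its call (adjusted p = 0.0389) was lost at adjusted p = 0.413 with an estimated correlation.

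Genes of the actin cytoskeleton were higher with PD0325901 than in CMAF. Their list was also higher with BMP4 and with SB431542 in EpiSC-5, which share CMAF arrays with this comparison. Of 14 actin and SRF targets, 12 rose and none fell (mean 2.08, 95% interval 1.91 to 2.26; adjusted p = 3.83e-14; 0.000442 with an estimated correlation). Feeder fibroblast genes, a list that shares Acta2 and Tagln with it, rose as well (7 of 12; mean 1.36; adjusted p = 0.000518; lost at adjusted p = 0.0724 with an estimated correlation). Smooth muscle actin Acta2 rose by 5.95 ± 0.29 and skeletal actin Acta1 by 5.44 ± 0.23. Cryab, Lgals3, Anxa3, Wnt4 (4.65 ± 0.22), Igf2 (4.29 ± 0.31), Gbp2 and Pmp22 were also among the highest. Of 10 naive pluripotency genes, Klf2 (4.24 ± 0.18), Klf5 (2.14 ± 0.20) and Tfcp2l1 (2.29 ± 0.14) rose, and the other 7 did not pass, among them Esrrb (0.08 ± 0.15) and Klf4, detected on 0 of 22 PD0325901 arrays and on 1 of 36 CMAF arrays. That list was called at adjusted p = 0.0247 and lost at adjusted p = 0.125 with an estimated correlation. Trh fell by 5.69 ± 0.46, and Pdk1 (-3.25 ± 0.23), Tdgf1 (-2.61 ± 0.21), Bcl11b, Pla2g10, Mgarp, Ppp1r3g and Hopx were also among the lowest. Stc1, below detection on all 22 PD0325901 arrays, was at least 5.04-fold lower. Of 15 glycolysis and hypoxia genes, 13 fell and 1 rose (adjusted p = 1.41e-07; adjusted p = 0.0724 with an estimated correlation). PD0325901 arrays of EpiSC-5 detected 28.7% ± 2.58 of probes (SD, n = 10) against 33.9% ± 1.90 in EpiSC-G (SD, n = 12). The count was 3863 in EpiSC-5 alone and 2223 in EpiSC-G alone.

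Embryoid bodies are aggregates grown without the factors that hold cells in the epiblast state. Over the mean of both lines they changed the most genes in the factorial panel, with 1461 higher and 1764 lower (38 arrays). In EpiSC-5 alone they changed 3319, fewer than PD0325901 (3863). For the mean of both lines the total was 1669 without background correction and 947 with the authors' value table. Of 10 core pluripotency genes, 6 fell and 2 rose (mean -1.85, 95% interval -1.95 to -1.75; adjusted p = 0.000681; 0.00744 with an estimated correlation). Pou5f1, which encodes Oct4, fell by 6.18 ± 0.17 (adjusted p = 7.61e-78, limma), and it was detected on 15 of 38 embryoid body arrays and on all 36 CMAF arrays. Utf1 fell by 5.76 ± 0.19, L1td1 by 5.56 ± 0.19, Cldn6 by 5.21 ± 0.17, Lefty1 by 5.09 ± 0.29 and Nodal by 4.15 ± 0.19. Dok2, Rab25, Olig1 and Vrtn were the others of the 10 lowest. Of 10 primed epiblast genes, 5 fell and none rose (adjusted p = 0.000681; 0.026 with an estimated correlation).

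Neural genes rose in embryoid bodies. Of 12 neuroectoderm genes, 8 rose and 1 fell (mean 1.22, 95% interval 1.12 to 1.33; adjusted p = 0.00129; 0.026 with an estimated correlation). Sox21 rose by 6.11 ± 0.27, pleiotrophin (Ptn) by 5.96 ± 0.21, Crabp1 by 5.58 ± 0.18, Crabp2 by 5.15 ± 0.25, Meis2 by 5.09 ± 0.24 and the forebrain gene Otx1 by 4.57 ± 0.20. Pdzph1, Ildr2, Lix1 and Flrt3 were also among the highest. Of 15 primitive streak and mesoderm genes, Wnt3a rose (2.21 ± 0.20), while Mixl1 (-0.87 ± 0.16) and Wnt3 (-0.83 ± 0.14) fell. Eomes, detected on 0 of 38 embryoid body arrays and 11 CMAF arrays, passed at adjusted p = 1.56e-09. In definitive endoderm, the chemokine receptor gene Cxcr4 rose by 3.13 ± 0.17 and Foxa3 fell by 2.11 ± 0.11, while Sox17 (-0.12 ± 0.10) and Foxa2 (-0.15 ± 0.07) did not pass. Of 11 extraembryonic endoderm genes, Apoe (1.86 ± 0.08), Dab2 (1.04 ± 0.10) and Col4a2 rose and 8 did not pass. Fgf8, at -0.05 ± 0.22 over both lines, was at 0.78 in EpiSC-G alone, where it passed. Nodal and Activin targets (8 of 11 fell), FGF and ERK targets (9 of 15 fell, 3 rose) and glycolysis and hypoxia genes (10 of 15 fell) were called, at adjusted p = 0.0921, 0.328 and 0.301 with an estimated correlation.

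**Figure D1:**
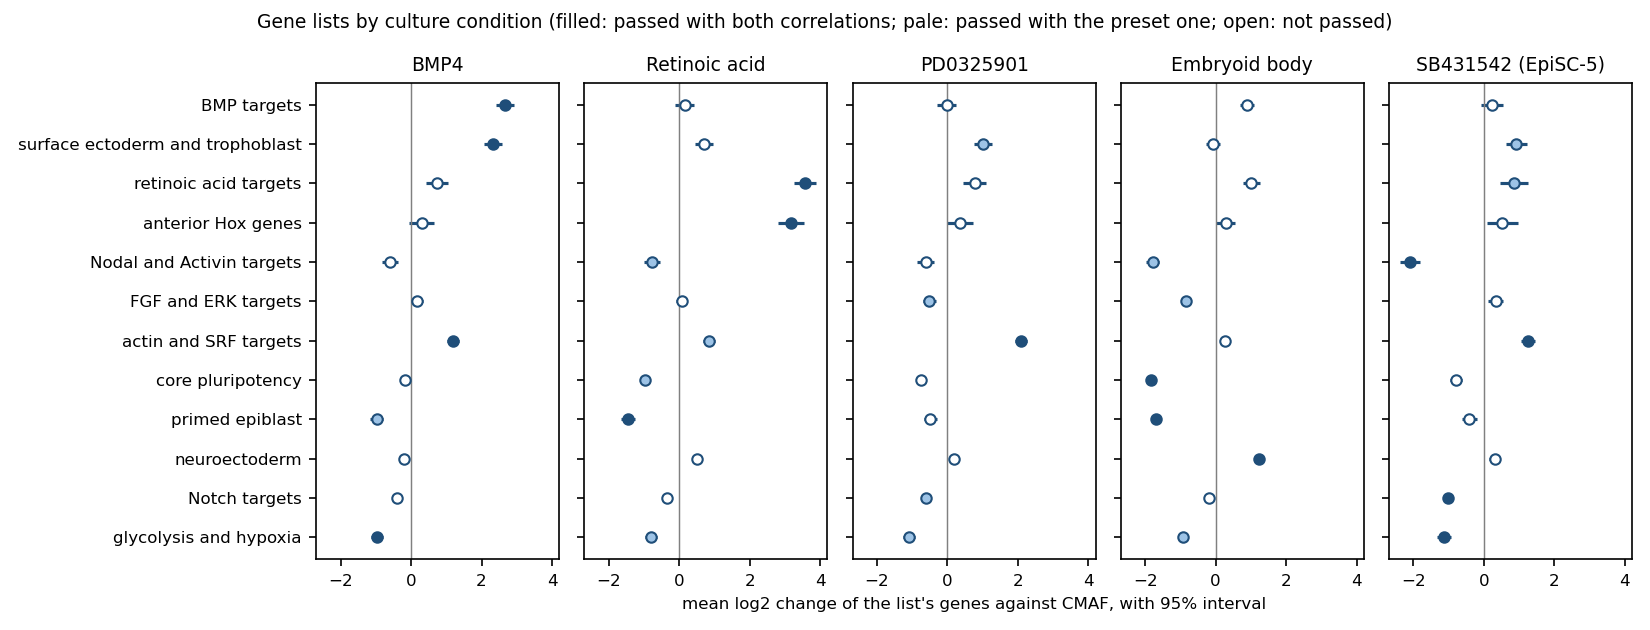
Mean log2 change of 12 gene lists against CMAF in the factorial panel, with 95% intervals, for each of 5 conditions (the SB431542 values are from EpiSC-5). BMP targets stood at 2.67 with BMP4, retinoic acid targets at 3.57 with retinoic acid, and Nodal and Activin targets at -2.10 with SB431542.

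SB431542 blocks the receptors of Activin and Nodal, which hold the epiblast state. In EpiSC-5 it raised 948 genes and lowered 939 (12 and 19 arrays), in all 804 without background correction and 438 with the authors' value table. Of 11 Nodal and Activin targets, 9 fell, or 10 adjusted over the list alone, and none rose. The feedback inhibitor Lefty1 fell by 7.40 ± 0.47 (adjusted p = 1.35e-31, limma), to a level detected on 2 of 12 arrays. Nodal itself fell by 3.58 ± 0.30, its co-receptor gene Tdgf1 by 3.11 ± 0.25, Fgf8 by 1.79 ± 0.35 and Skil by 0.69 ± 0.14. Lefty2, below detection on all 12 SB431542 arrays, was at least 5.12-fold lower. The list mean was -2.10 (95% interval -2.38 to -1.82; adjusted p = 3.16e-08; 0.00243 with an estimated correlation). Nanog, a direct target of the pathway in these cells, fell by 4.47 ± 0.33, and Trh by 7.58 ± 0.54. Fgf15, Bcl11a and Stc1 were also among the lowest.

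Of 10 Notch targets, 6 fell and 1 rose with SB431542 (mean -1.02, 95% interval -1.14 to -0.91; adjusted p = 3.09e-07; 0.000104 with an estimated correlation), and Hey1 fell by 3.09 ± 0.16. Neuroectoderm genes went both ways. Gbx2 rose by 4.13 ± 0.42 and Nes by 1.01 ± 0.18, Sox3 fell by 0.66 ± 0.16, and 9 of 12 did not pass. Fgfbp1 (5.06 ± 0.24), S100a6 (5.02 ± 0.22), Ahnak (5.16 ± 0.30), Anxa3 (5.15 ± 0.30), Meis2, Lgals3, Gadd45g, Pmp22 and the actin-binding gene Cald1 were the highest with Gbx2. Actin and SRF targets (9 of 14 rose), glycolysis and hypoxia genes (12 of 15 fell, 1 rose) and extraembryonic endoderm genes (5 of 11 rose) passed with both correlations. Feeder fibroblast genes (5 of 12 rose, 1 fell) passed at adjusted p = 0.0371 and were lost at adjusted p = 0.229 with an estimated correlation. For naive pluripotency (3 rose, 2 fell of 10) the mean was 0.64 and the median -0.003; its call was lost at adjusted p = 0.156 with an estimated correlation.

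Arrays labelled with no morphogen differed from CMAF by 1016 higher and 695 lower genes (34 and 36 arrays), in all 717 without background correction and 395 with the authors' value table. Retinoic acid targets (11 of 16 rose; mean 2.42, 95% interval 2.10 to 2.73; adjusted p = 1.34e-12) and anterior Hox genes (11 of 12 rose; mean 2.24; adjusted p = 1.53e-10) were higher, at adjusted p = 0.00835 and 0.028 with an estimated correlation. Meis2 rose by 5.33 ± 0.32, Hoxa5 by 5.28 ± 0.42, Pmp22 by 4.81 ± 0.32, Tshz1 by 4.61 ± 0.30, Crabp2 by 4.51 ± 0.34 and Cyp26a1 by 3.79 ± 0.45. Of 15 imprinted genes, 9 rose (adjusted p = 1.37e-06; 0.00835 with an estimated correlation). Feeder fibroblast genes (6 of 12 rose, 1 fell) passed at adjusted p = 0.0124 and were lost at adjusted p = 0.148 with an estimated correlation. Otx2 fell by 2.21 ± 0.22, Nanog by 2.36 ± 0.27 and Tdgf1 by 2.34 ± 0.20, with Ankrd37, Stc1, Trh, Jakmip1, Fgf15, Bcl11a and Hopx. These arrays are not alike: Hoxa5 was detected on 28 of 34, with a signal of 9.44 ± 2.86 (SD). Among the 32 arrays with neither morphogen nor compound, 10 were closest, over all genes, to an array of another condition. The labels do not say what medium these cells were in.

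**Figure D2:**
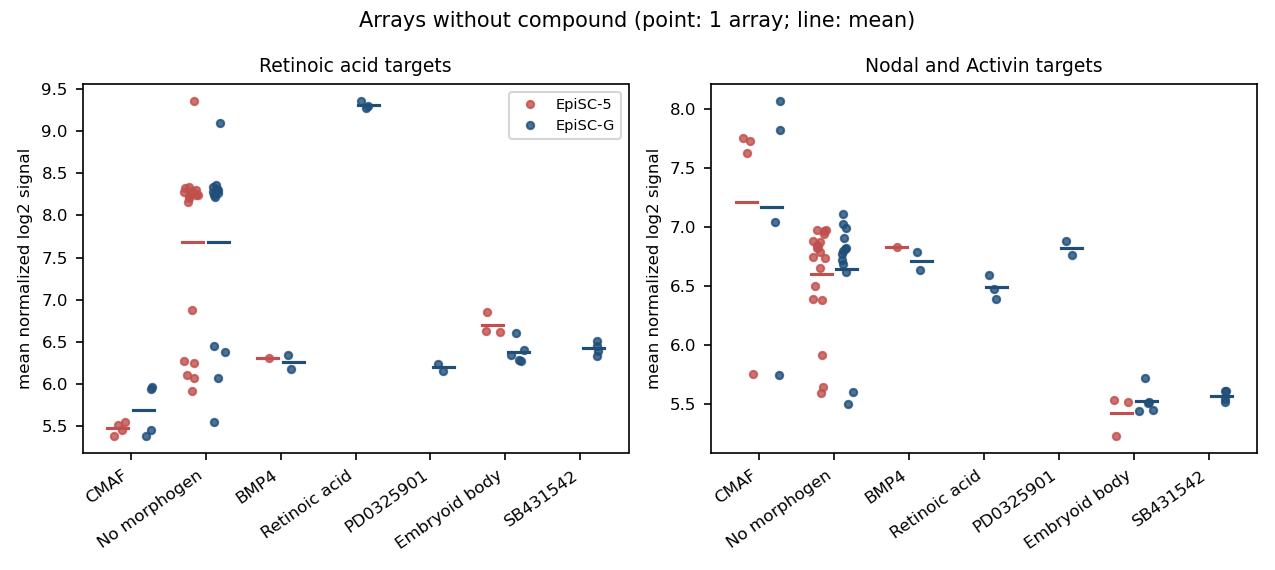
Mean normalized log2 signal of retinoic acid targets and of Nodal and Activin targets on each array without compound, by labelled condition and line, with group means as lines. Arrays labelled with no morphogen spread from 5.55 to 9.36 for retinoic acid targets.

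Between the lines in CMAF, 189 genes were higher and 260 lower in EpiSC-5 (19 and 17 arrays). The total of 449 fell to 142 without background correction, where 31.7% were higher against 42.1%, and to 65 with the authors' value table. The largest differences were losses in EpiSC-5. Fbxw17 was lower by -4.31 ± 0.32, the acyl-CoA thioesterase gene Acot1 by -4.25 ± 0.35 and the imprinted growth inhibitor Cdkn1c by -3.99 ± 0.38 (adjusted p = 1.92e-17, limma). Rtl6, Klhl22, Cxcl16 and Repin1 were below detection on all 19 EpiSC-5 arrays and on none of the 17 of EpiSC-G, and were at least 6.10-, 3.83-, 2.99- and 2.90-fold lower. Of 15 imprinted genes, Cdkn1c, Rian (-1.30 ± 0.20) and Peg3 (-1.06 ± 0.22) were lower and none was higher. Krt8, Krt18 and Krt19 were lower by -0.75 ± 0.25, -0.70 ± 0.22 and -0.89 ± 0.18, Klf5 by -1.42 ± 0.21, Acta2 by -1.20 ± 0.30, Anxa3 by -2.23 ± 0.27 and S100a6 by -2.21 ± 0.19. The neurofilament gene Nefm was at least 1.36-fold lower in EpiSC-5.

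Neither core pluripotency nor primed epiblast nor Nodal and Activin targets were called as lists between the lines. Single genes were higher in EpiSC-5: Lefty1 by 1.53 ± 0.42, Lefty2 by 1.55 ± 0.28, Nanog by 0.90 ± 0.30 and Sox2 by 0.71 ± 0.18. Ncam1 (1.24 ± 0.17), Gbx2 (1.24 ± 0.38), Hey1 (1.11 ± 0.14), Zeb1 (1.11 ± 0.16) and Rxrg (1.10 ± 0.14) were also higher, with Ankrd37, Coro2b and Ifrd2. Pou5f1 (0.11 ± 0.24), Fgf5 (-0.61 ± 0.32) and Otx2 (0.56 ± 0.24) did not pass. Of the lists, Notch targets (3 of 10 higher; adjusted p = 0.00116) and cholesterol biosynthesis (2 of 11 higher; adjusted p = 0.000127) were higher in EpiSC-5, and heat shock genes (1 of 11 lower; adjusted p = 0.0181) were lower. These held at adjusted p = 0.025, 0.0256 and 0.0256 with an estimated correlation. Line went largely with the position on the slide in the factorial panel, so the design does not separate them.

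Interaction terms of line and condition passed for 250 genes with BMP4, 1822 with retinoic acid, 3361 with PD0325901 and 1125 with embryoid body. S100a6 rose more in EpiSC-5 than in EpiSC-G with BMP4 (4.70 ± 0.23 against 2.40 ± 0.23), retinoic acid (4.30 ± 0.25 against 0.64 ± 0.23) and PD0325901 (5.11 ± 0.25 against 2.69 ± 0.24). In CMAF it was lower in EpiSC-5 by about as much as the lines differ in their BMP4 and PD0325901 responses. Those 2 differences thus largely restate the CMAF levels, and all conditions share the CMAF arrays. Phlda1 rose by 4.13 ± 0.31 with retinoic acid in EpiSC-5 and by 0.53 ± 0.28 in EpiSC-G. Rec8, a meiotic cohesin, rose by 3.67 ± 0.20 in EpiSC-G and 0.72 ± 0.22 in EpiSC-5, and the hypoxia-linked Aldoc rose in EpiSC-G (1.04 ± 0.24) and was at -1.96 ± 0.26 in EpiSC-5. In embryoid bodies the neural genes Zic1 (4.61 ± 0.21 against 0.83 ± 0.21) and En2 (3.19 ± 0.27 against -0.15 ± 0.26) rose more in EpiSC-G. Fgfbp1 rose in EpiSC-5 (2.62 ± 0.21) and was at -1.76 ± 0.21 in EpiSC-G. With PD0325901 the chromosome genes Smc2 (-2.80 ± 0.24) and Stag2 (-2.58 ± 0.21) fell in EpiSC-5, against 0.21 ± 0.23 and 0.40 ± 0.20 in EpiSC-G. The EpiSC-5 PD0325901 arrays also detected fewer probes than the EpiSC-G array of the same slide on 9 of 9 slides, by a median of -5.27 points, so these differences are not read as a response of the line. Without background correction the counts were 83 for BMP4, 785 for retinoic acid, 1664 for PD0325901 and 410 for embryoid body, and with the authors' value table they were 50, 401, 936 and 217. For BMP4 it was 151 without the Wnt agonist arrays, and the share higher in EpiSC-5 moved from 60.8% to 76% with the authors' value table.

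In EpiSC-G, SB431542 was compared with the arrays labelled with no morphogen in its own batches (4 and 6 arrays). These controls are not alike. Their mean log2 signal of retinoic acid targets was 6.07 and 6.45 on replicates 4 and 5, and 8.22 to 8.36 on the others. Differences from them therefore also reflect what is on the control arrays. With SB431542, 325 genes were higher and 398 lower. The total was 214 without background correction, 98 with the authors' value table and 252 with the slide as a fixed block. Of 11 Nodal and Activin targets, 5 fell and none rose (mean -1.20, 95% interval -1.31 to -1.08; adjusted p = 2.06e-17; 3.87e-19 with an estimated correlation). Lefty1 fell by 4.86 ± 0.20 (adjusted p = 1.84e-29, limma), Nodal by 3.73 ± 0.25 and Trh by 3.60 ± 0.26, and Fgf8 was at least 2.97-fold lower. Skil (-0.20 ± 0.15) did not pass, nor did Tdgf1 and Eomes, which were detected on 0 of the 4 SB431542 arrays. Foxd4 rose by 2.85 ± 0.41, the ERK phosphatase gene Dusp4 by 1.85 ± 0.13 and the imprinted Rian by 1.81 ± 0.24, with Cdhr1, Rif1, Adamts15, Fbxo15, Tgm1, Snrnp70 and Gadd45b. Anterior Hox genes were lower (11 of 12; adjusted p = 1.31e-10; adjusted p = 0.0878 with an estimated correlation). Hoxb5, Ednrb, Zfp703, Dbx1 and Grifin were detected on 4 of 6 no-morphogen arrays and on no SB431542 array. The number of genes changed by SB431542 against no morphogen in EpiSC-G was 1157 without replicate 4 and 1120 without replicate 5 of the no-morphogen arrays, and 163 in batch 81 alone. Other splits of the 10 arrays gave up to 1044 genes, so chance is not excluded for this count. Because the controls are not alike, other splits may also gain genes from differences among them, so the splits cannot decide.

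Against the 2 CMAF arrays of these batches, SB431542 raised 709 genes and lowered 581 in EpiSC-G. Of 11 Nodal and Activin targets, 10 fell (mean -2.38, 95% interval -2.53 to -2.24; adjusted p = 1.34e-36, limma). Lefty1 fell by 5.64 ± 0.26, Trh by 5.47 ± 0.33 and Nodal by 4.79 ± 0.32, while Fgf8, Lhx1 and Gsc were at least 12.6-, 9.98- and 7.80-fold lower. Gbx2 rose by 3.42 ± 0.52, Gadd45g by 2.75 ± 0.22, the glucose transporter gene Slc2a1 by 2.49 ± 0.11, and Foxd4 was at least 22.4-fold higher. Hoxa5 (1.00), Ednrb (0.32) and Grifin (0.02), which were lower than on no-morphogen arrays, were not lower than in CMAF, and Rif1 (-0.12) was not higher.

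Each of 36 compounds was compared with SB431542 alone. In all, 14 changed 50 or more genes, 11 changed none and 11 changed 1 to 49. BMP4 (1103 higher, 867 lower), retinoic acid (692 and 769), indolactam, a protein kinase C activator (262 and 290), PD0325901 (221 and 328), the histone deacetylase inhibitor valproic acid (328 and 184) and the FGF receptor inhibitor SU5402 (161 and 141) led. Rapamycin, IPA-3, genistein, forskolin, purmorphamine, (5Z)-7-oxozeaenol, Wnt agonist and wortmannin followed. Against the mean of all other SB431542 groups of the same batch, with and without compound, the last 4 of these changed 22, 28, 18 and 0 genes by limma (wortmannin: 719 at an unadjusted p under 0.05). FGF2 (65) and Y-27632 (51) came to 50 or more there, so that 12 compounds did. For FGF2 (batch 81) the mean includes the BMP4 and retinoic acid groups. BMP4 raised 9 of 10 BMP targets even with SB431542 present, Msx1 by 5.73 ± 0.31 and Id1 by 4.85 ± 0.41 (adjusted p = 2.38e-13, limma), and lowered Fgf5, Foxd4 and Cyp26a1 by at least 17.5-, 18.1- and 8.07-fold. Retinoic acid raised 13 of 16 retinoic acid targets and lowered 1. Otx2, below detection in its 2 arrays, was at least 32.3-fold lower. With the authors' value table, 6 compounds, and with a 2-fold minimum 8, changed 50 or more genes.

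Compounds that act on a pathway moved its target genes to differing degrees. PD0325901 lowered 9 of 15 FGF and ERK targets (mean -1.37, 95% interval -1.53 to -1.22), Etv5 by -3.23 ± 0.18 and Dusp6 by -3.20 ± 0.16 among them. SU5402 lowered 6 (mean -0.58, 95% interval -0.73 to -0.42), with Dusp4 at -1.90 ± 0.18 and Etv4 at -1.82 ± 0.18. Forskolin, which raises cAMP, raised Pde4d by 3.39 ± 0.24 and Pde4b by 1.26 ± 0.23 of 8 cAMP targets. LIF changed 1 gene, Socs3, a feedback inhibitor of STAT3 (1.41 ± 0.19; adjusted p = 2.8e-06), and the STAT3 target list was higher (mean 0.42, 95% interval 0.23 to 0.60; adjusted p = 5.41e-08). The ROCK inhibitor Y-27632 lowered Acta1 (-1.37 ± 0.18) and Ankrd1 (-1.03 ± 0.22), and Tagln by at least 2.22-fold. The Hedgehog agonist purmorphamine raised Ptch1, the pathway's receptor and target, by 1.21 ± 0.22. Dorsomorphin changed Acta1 (1.08 ± 0.18) and Tgm1 (1.23 ± 0.22). IWP-2 changed Dph3 alone, KT5720 Nudt22, locostatin Slc7a7 and Telomerase Inhibitor 3 Adssl1, while the G9a inhibitor Bix01294 changed Uap1l1, Slpi, Cdkn2a, Trnp1 and Arrdc4. These counts also depend on the control. Against the mean of all other groups of the same batch they were 39 for Telomerase Inhibitor 3, 38 for Bix01294 and 13 for dorsomorphin. LIF had 5 there, KT5720 2, locostatin 1 and IWP-2 0 (387 at an unadjusted p under 0.05 by limma).

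The strongest compounds also moved genes outside their pathways. SU5402 raised Shisa2 by 3.43 ± 0.24 and Cyp26a1 by 2.53 ± 0.36 and lowered Trh (-3.14 ± 0.36) and Olig1 (-2.60 ± 0.21). Gbx2 fell with indolactam (-2.38 ± 0.57), SU5402 (-2.54 ± 0.55) and IPA-3 (-2.57 ± 0.56), all against the same 4 arrays of SB431542 alone, which spread widely for this gene (10.9 ± 1.76, SD), so these are not independent. The antioxidant gene Nqo1 rose with IPA-3 (1.71 ± 0.22). With valproic acid, Slpi (2.01 ± 0.21) and Dnmt3l (1.99 ± 0.44) rose and Cxcl12 fell (-2.14 ± 0.39). Its 2 arrays differed, with an SD of 2.91 for Dnmt3l, whose change was -0.05 without replicate 1.

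For 11 compounds limma called no gene: a pair of compounds not named here (429 and 660 genes at an unadjusted p under 0.05), DAPT (404), dexamethasone (913), docetaxel (1072), FGF2 (641), IDE-1 (559), KAAD-cyclopamine (823), LDN-193189 (446), olomoucine (678) and the STAT3 inhibitor (475). These counts of 0 depend on the control: against the mean of all other groups of the same batch limma called 65 genes for FGF2, 25 for docetaxel, 23 for dexamethasone, 12 for IDE-1, 14 for 1 of the unnamed pair, 2 to 4 for DAPT, KAAD-cyclopamine, LDN-193189 and the STAT3 inhibitor, and 0 for olomoucine (591 at an unadjusted p under 0.05) and the other of the pair (587). Most of their target lists lay near 0, as for DAPT and Notch targets (-0.05, 95% interval -0.21 to 0.12), cyclopamine and Hedgehog targets (0.07, -0.09 to 0.22) and dexamethasone and glucocorticoid targets (0.06, -0.05 to 0.18). FGF2 was an exception, with FGF and ERK targets at 0.27 (95% interval 0.12 to 0.42, cameraPR adjusted p = 0.00136). Olomoucine was another, with p53 targets at 0.17 (95% interval 0.04 to 0.30, cameraPR adjusted p = 0.00608). Its call was lost at adjusted p = 0.107 with an estimated correlation. STAT3 targets with the STAT3 inhibitor were at 0.18 (95% interval -0.004 to 0.36).

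**Figure D3:**
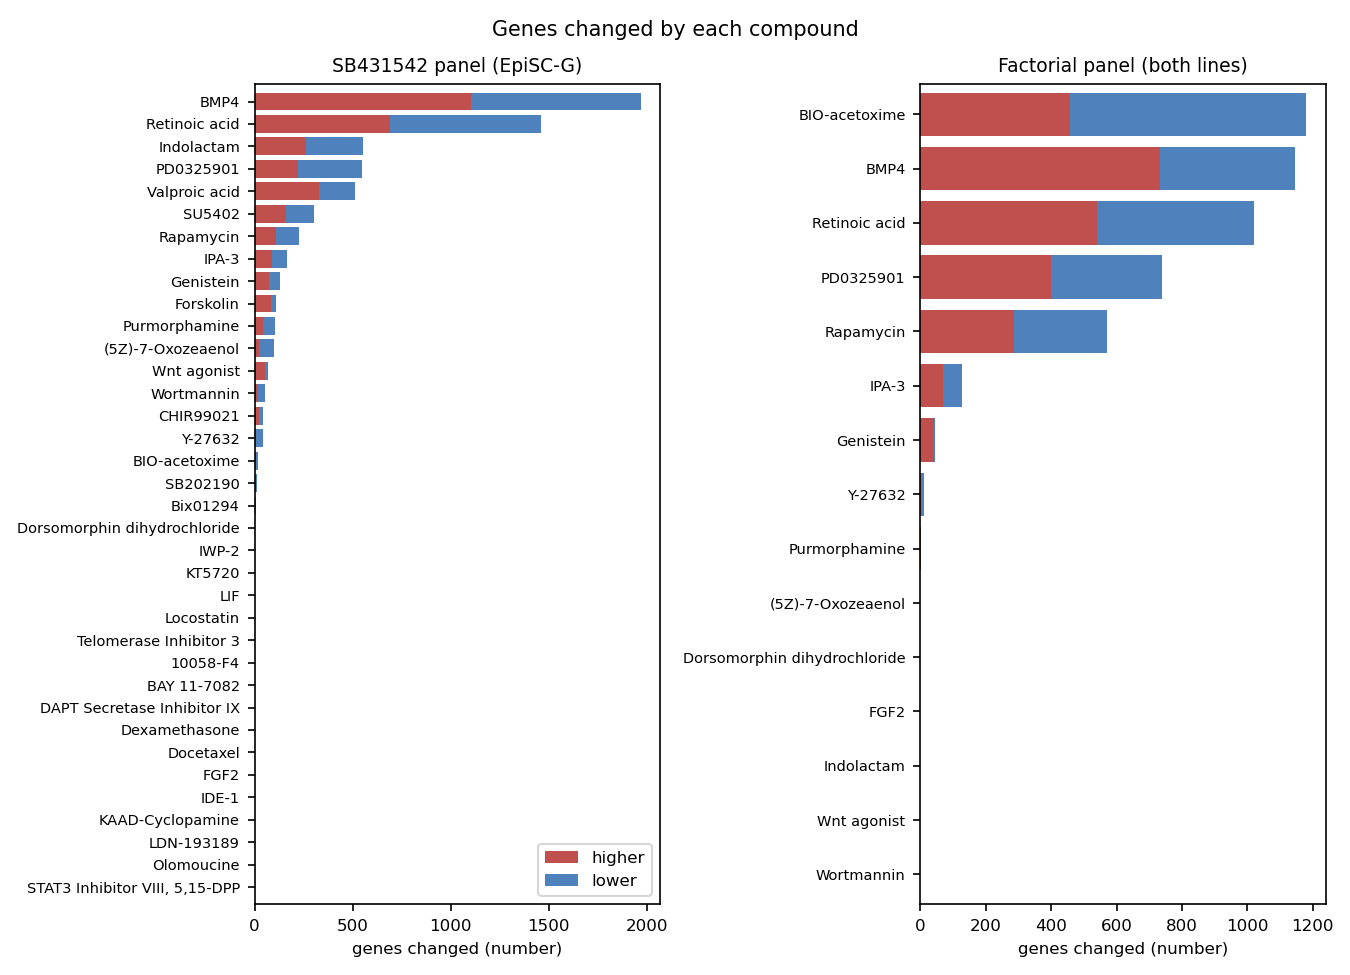
Number of genes that rose and fell with each compound, against SB431542 alone in the SB431542 panel and against no compound in the factorial panel. BMP4 changed 1970 genes in the first, and BIO-acetoxime 1180 in the second.

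In the factorial panel, 6 of 15 compounds changed 50 or more genes over the lines and conditions in which each was given. BIO-acetoxime, a GSK3 inhibitor that activates Wnt signalling, raised 459 genes and lowered 721 (11 arrays). Of 13 Wnt targets, 12 rose (mean 2.48, 95% interval 2.15 to 2.81; adjusted p = 3.43e-35, limma). Sp5 rose by 5.26 ± 0.50 and Axin2 by 3.68 ± 0.38, and Cdx1, below detection on all 48 comparison arrays, was at least 8.79-fold higher. The pluripotency gene Utf1 fell by 3.44 ± 0.40 and Pou3f1 by 3.06 ± 0.32. In the SB431542 panel the same dose of 5 µM changed 16 genes, and the Wnt target mean was 0.17 (95% interval -0.04 to 0.39). BMP4 (733 higher, 412 lower), retinoic acid (541 and 479), PD0325901 (400 and 339), rapamycin (286 and 284) and IPA-3 (70 and 59) also passed 50. Within the lines, rapamycin changed 1258 genes in EpiSC-5 and 143 in EpiSC-G, PD0325901 900 and 499, and IPA-3 275 and 70. Differences between the lines were not tested for these compounds. The EpiSC-5 rapamycin arrays include the array with the fewest probes detected of all (23.8%). IPA-3 had fewer arrays in EpiSC-5, all on slide 26. As a compound, PD0325901 lowered 8 of 15 FGF and ERK targets and raised none (mean -1.09, 95% interval -1.35 to -0.83), and Egr1 fell by 3.83 ± 0.31. Y-27632 lowered 4 of 14 actin and SRF targets (mean -0.75, 95% interval -1.02 to -0.47), Acta2 by -2.28 ± 0.45. Purmorphamine changed 1 gene, Ptch1 (1.22 ± 0.21). No gene was called by limma for (5Z)-7-oxozeaenol (518 at an unadjusted p under 0.05), dorsomorphin (1194), FGF2 (767), indolactam (415), Wnt agonist (284) or wortmannin (242). In EpiSC-5 alone, dorsomorphin changed 12 genes.

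Compounds with a shared target were set side by side in the SB431542 panel. LDN-193189 (600 nM) and dorsomorphin (2 µM), both inhibitors of BMP receptors, differed in 7 genes, all higher with LDN-193189, Egfl7 by 1.01 ± 0.18 and Riox1 by 0.94 ± 0.15 (2 and 2 arrays). Ddr1, at 1.02 ± 0.18, was at -0.38 with its second probe. The median 95% half-width was 0.45, and 92.5% of genes lay within 2-fold by their interval. BMP targets differed by -0.03 (95% interval -0.31 to 0.25). Against SB431542 alone neither compound moved them: -0.03 (-0.29 to 0.24) with LDN-193189 and 0.001 (-0.26 to 0.26) with dorsomorphin. Their likeness therefore says nothing about a shared action. CHIR99021 (3 µM) and BIO-acetoxime (5 µM), both inhibitors of GSK3, differed in 90 genes (51 higher and 39 lower with CHIR99021). Pdzk1 (1.84 ± 0.28) and Igtp (1.76 ± 0.32) were higher and Il24 (-1.84 ± 0.34) and Slc7a7 (-1.55 ± 0.29) lower. Wnt targets differed by -0.22 (95% interval -0.51 to 0.06). Against SB431542 alone they were at -0.05 (-0.28 to 0.18) with CHIR99021 and 0.17 (-0.04 to 0.39) with BIO-acetoxime, so the same limit holds. The doses differ, and each GSK3 inhibitor lies in its own batch, so the difference between these inhibitors rests on the batch term. Leaving out single arrays gave 0 to 4 genes for the first pair and 10 to 41 for the second. The second pair gave 49 without a slide block and 639 with the slide as a fixed block.

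Dorsomorphin was also asked to block BMP4. With both present (2 arrays), BMP targets lay below the sum of the separate effects by -0.76 ± 0.37 (upper end of the 95% interval -0.02), against a BMP4 effect of 2.72. Both arrays lay on slide 40, which held no other array of the BMP4 condition, so this value rests on 1 slide. Msx1 (-2.34 ± 0.86), Gata2 (-2.27 ± 0.69), Gata3 and Id4 (-1.06 ± 0.29) lay lower, while Id1 (0.80 ± 0.95), Id2 (0.33 ± 0.52) and Id3 (0.40 ± 0.70), immediate targets, did not. Smad6 (-0.62 ± 0.38), Hey1 (-0.42 ± 0.37) and Dlx5 (-0.40 ± 0.26) had intervals that included 0. The interval of the list mean included 0 without a slide block (-0.69), with a stricter detection filter (-0.56) and with none (-0.50). It also did in 6 of 14 refits that each left out the arrays of 1 compound.

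For 15 compounds used in both panels, which share no arrays, the profile of log2 changes was correlated across the 11527 genes, which are not independent replicates. The mean Pearson's r of a compound with itself was 0.20, against 0.0667 between different compounds (one-sided permutation test of the names, p = 4e-05). Retinoic acid (r = 0.719), BMP4 (r = 0.685) and PD0325901 (r = 0.498) were closest to themselves; BIO-acetoxime (r = 0.347), rapamycin (r = 0.324) and wortmannin (r = 0.168) were each closer to 1 other compound, and indolactam had the lowest value (r = -0.138). With rapamycin, an mTOR inhibitor, Ddit4 fell by 2.25 ± 0.25 in the factorial panel and by 2.40 ± 0.26 in the SB431542 panel, Cbr3 by 2.08 ± 0.22 and 2.43 ± 0.16, and Chac1 by 1.54 ± 0.21 and 2.29 ± 0.30.

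**Figure D4:**
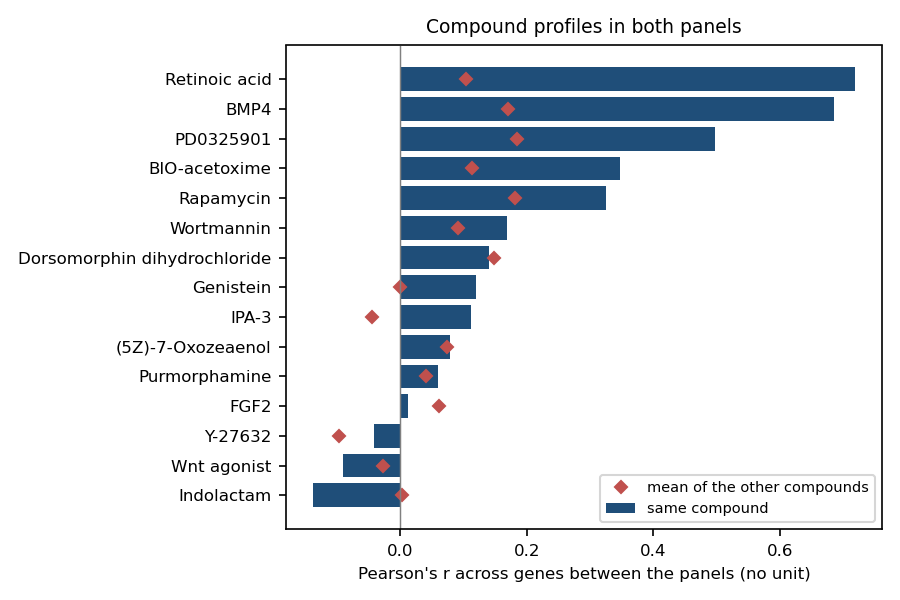
Pearson's r across genes between the panels for each of 15 compounds (bars), with the mean r to the other compounds (diamonds). The bars run from -0.138 for indolactam to 0.719 for retinoic acid.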

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

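Of the tests in this part, the comparison of probes detected on arrays of the same slide was chosen after the result was seen.

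Dixon's test was applied 36 times, to 9 measures in each of 4 groups of 4 or 5 arrays without compound. It was met 4 times; chance flags about 1 in 20 groups. The library labelled EpiSC-G embryoid body without compound, replicate 2, had a core pluripotency level of 7.62 (mean normalized log2 signal of the list) and a Nodal and Activin target level of 5.72, the highest of its group in both. Both also lay above the EpiSC-5 embryoid body arrays without compound (highest 7.59 and 5.53). Its FGF and ERK target (7.40) and feeder fibroblast (5.91) levels lay within those EpiSC-5 arrays (7.347 to 7.725 and 5.72 to 5.94). The rest of its own group had 7.77 to 8.16 and 6.19 to 6.91. Whether its line label is right was not tested, and it stayed in the EpiSC-G group. The library labelled EpiSC-5 CMAF without compound, replicate 4, had a neuroectoderm level of 6.42, and its Nodal and Activin target level of 5.75 lay far below 7.63, the next lowest of its group. The EpiSC-G array labelled CMAF on the same slide had a Nodal and Activin target level of 5.74.

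Interaction terms of line and condition passed, by limma, for 250 genes for BMP4, 1822 for retinoic acid, 3361 for PD0325901 and 1125 for embryoid body. Values are the EpiSC-5 minus the EpiSC-G response on the log2 scale. With BMP4 the response was higher in EpiSC-5 for Anxa3 (2.32), S100a6 (2.30), Phlda1 (2.15), Fgfbp1 (2.07) and Ahnak (2.05) and lower for Wnt6 (-1.55), Cxcl16 (-1.44), Lefty2 (-1.41), Stard8 (-1.26) and Tns1 (-1.22). In CMAF, Anxa3 and S100a6 were lower and Lefty2 higher in EpiSC-5 by about these amounts. For these genes the difference with BMP4 largely restates the CMAF levels. With retinoic acid it was higher for S100a6 (3.66), Phlda1 (3.60), Anxa3 (3.55), Gbp2 (3.40) and the small heat shock gene Hspb1 (3.37) and lower for Foxd4 (-3.12), Aldoc (-3.00), Rec8 (-2.95), Smoc1 (-2.79) and Pdzk1 (-2.64).

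With embryoid body the response was higher in EpiSC-5 for Fgfbp1 (4.38), Cyp26a1 (3.63), Upp1 (3.35), the tight junction gene Cldn4 (3.33) and Mup6 (3.30) and lower for Zic1 (-3.78), Tmem132c (-3.47), En2 (-3.34), Trh (-3.04) and the Wnt modulator Rspo3 (-3.00). With PD0325901 it was higher for Fgfbp1 (2.56), S100a6 (2.42), the metallothionein gene Mt1 (2.20), Hspb1 (2.16) and Chmp4b (2.12) and lower for Zdhhc21 (-3.10), Smc2 (-3.01), Stag2 (-2.98), Thoc2 (-2.95) and Sgo2a (-2.93).

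The PD0325901 differences were weighed further. A response that differs between the lines was predicted to appear also where PD0325901 was given as the compound. Over the 1738 genes with a lower response in EpiSC-5, the median interaction was -1.10. With PD0325901 as the compound, the median difference between the lines over these genes was -0.018 (quartiles -0.16 to 0.13). The position of these arrays on the slide is argued against by the other 22 EpiSC-5 arrays in the same position, which had a median of 32.3% of probes detected, against 29.5% for PD0325901. Lower RNA quality on the EpiSC-5 PD0325901 arrays may contribute: they detected fewer probes than the EpiSC-G PD0325901 array on 9 of 9 slides, by a median of -5.27 points (-8.25 to -2.44). The test with PD0325901 as the compound rests on 5 and 4 arrays, with 36 hours of exposure against 24 for the condition. Some of these arrays in both lines carry the no-morphogen label, whose arrays are not alike. The others were in CMAF, embryoid body culture or SB431542. No such difference was seen there, but the test cannot decide whether the lines respond differently in the PD0325901 condition.

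Labels were split 100 ways, within line for conditions, within condition for lines, and within line and condition for compounds. The real grouping is 1 of the 100 and is counted in each number of splits, so 1 means that no other split reached it. As many genes as in the real grouping came from 1 split for BMP4 (1791 genes, highest other 18), 1 for retinoic acid (2028, 308), 1 for PD0325901 (2572, 138), 1 for embryoid body (3225, 388), 1 for SB431542 in EpiSC-5 (1887, 453), 1 for no morphogen (1711, 271) and 1 for the lines in CMAF (449, 160). It was 2 splits for the line-dependent response to BMP4 (250, with a higher count in 1 other split) and 1 each for those to retinoic acid (1822, 525), PD0325901 (3361, 2752) and embryoid body (1125, 120). For compounds of the factorial panel it was 1 (6 compounds, highest other 2). Random relabelling thus seldom or never gave as many. The shuffles ignored the slide, so where conditions or compounds were grouped by slide they cannot tell these from slide differences. Some splits called many genes, up to 2752 for PD0325901, which points to structure among the arrays. For SB431542 against no morphogen in EpiSC-G, 6 splits, the real one among them, gave as many (723, highest other 1044), so chance cannot be excluded for that count. Its labels were shuffled across both batches, and its no-morphogen arrays are not alike. High counts in other splits may come from these differences, so this test cannot decide.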

How the results depend on the processing

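Each line alone from the same fit, and the fits without the no-morphogen arrays or without the CMAF arrays of 1 slide, were tests chosen after seeing the data. Of the counts and summary values under all alternatives, 506 stayed the same (counts within 1.5-fold, other values by their call), 48 moved and 9 became weaker. Of the values of named genes, 15523 kept direction and call, 511 became weaker, 81 stronger and 9 reversed. The cause was not tested.

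Without background correction, the counts were 852 for BMP4, 974 for retinoic acid, 1201 for PD0325901, 1669 for embryoid body, 804 for SB431542 in EpiSC-5, 717 for no morphogen, 142 for the lines and 214 for SB431542 in EpiSC-G. Line-dependent responses numbered 83, 785, 1664 and 410 for BMP4, retinoic acid, PD0325901 and embryoid body. With the authors' value table they were 491, 535, 666, 947, 438, 395, 65 and 98, and 50, 401, 936 and 217, in the same order; CHIR99021 against BIO-acetoxime gave 44 and 6 compounds of the SB431542 panel passed.

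The share of higher genes moved from 59.3% to 70.1% for BMP4 and from 52.2% to 62.3% for PD0325901 with the authors' table, and from 42.1% to 31.7% for the lines without background correction. For line-dependent responses it moved from 60.8% to 75.9% and 76% for BMP4 and from 48.3% to 35.9% and 25.5% for PD0325901, without background correction and with the authors' table.

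With a 2-fold minimum, 8 compounds of the SB431542 panel passed. On arrays without compound BMP4 gave 819, with fewer arrays. PD0325901 gave 3863 in EpiSC-5 alone. SB431542 in EpiSC-G gave 163 in batch 81 alone, 1290 against CMAF and 252 with the slide as a fixed block. CHIR99021 against BIO-acetoxime gave 49 without a slide block and 639 with a fixed one. LDN-193189 against dorsomorphin gave 4 without a filter, 3 without a slide block and 1 with the second probe. Dorsomorphin with BMP4 was -0.56 with the stricter filter, -0.50 with none and -0.69 without a slide block, with intervals that include 0.

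Reversed values were Ddr1 for LDN-193189 against dorsomorphin with the second probe (-0.38), Dnmt3l for valproic acid without replicate 1 (-0.047, against 4.03 without replicate 2), Fgf8 for embryoid body (0.78) and Nes for retinoic acid (-0.17) in EpiSC-G alone, and Gsc for BMP4 on arrays without compound (0.24). Against CMAF, Ednrb (0.32), Grifin (0.023), Hoxa5 (1.00) and Rif1 (-0.12) reversed for SB431542 in EpiSC-G.

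Leave-one-out ranges were 1755 to 1863 for BMP4, 1995 to 2131 for retinoic acid, 2481 to 2682 for PD0325901, 3092 to 3338 for embryoid body, 1831 to 1955 for SB431542 in EpiSC-5, 1679 to 2465 for no morphogen and 442 to 520 for the lines. Line-dependent responses gave 151 (without Wnt agonist arrays) to 316, 1729 to 1926, 3000 to 3605 and 1086 to 1167 for BMP4, retinoic acid, PD0325901 and embryoid body. SB431542 in EpiSC-G gave 581 to 1157 (without no-morphogen replicate 4). CHIR99021 against BIO-acetoxime gave 10 (without BIO-acetoxime replicate 2) to 41 (without replicate 1), and LDN-193189 against dorsomorphin 0 to 4, so every array matters there. Passing compounds numbered 12 to 16 and 5 to 6, list tests 117 to 126, the mean r 0.16 to 0.224 and dorsomorphin with BMP4 -0.79 to -0.72, with 6 refits whose interval includes 0.

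Arrays without compound could not give PD0325901, retinoic acid or SB431542 in EpiSC-5, whose cells are missing in EpiSC-5. The factorial panel left out each compound in place of each replicate. Arrays could not be paired by replicate, because the labels carry no replicate numbers that link arrays across conditions. Slides of the factorial panel hold arrays of both lines, and the slide entered the fits as a block. Only slides 15 and 25 held CMAF arrays together with arrays of the BMP4, retinoic acid or PD0325901 condition, and these CMAF arrays were of EpiSC-5. The design therefore hardly separates these conditions from the slide. Several slides also held 1 compound alone. Signal over background limits dim genes. Of 256 values of named genes with a second probe, 159 passed, and 129 of these passed with the second. Why the others did not was not tested.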

Other observations

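Of the tests in this part, those of BIO-acetoxime and that of the closest arrays were chosen after the result was seen.

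Most glycolysis and hypoxia genes fell in each condition compared with CMAF in the factorial panel. Of 15, 12 fell with BMP4, 10 with retinoic acid, 13 with PD0325901, 10 in embryoid bodies, 12 with SB431542 in EpiSC-5 and 10 with no morphogen, with means from -1.13 to -0.80. The call held with an estimated correlation for BMP4 (adjusted p = 0.0337, limma), SB431542 (0.0122) and no morphogen (0.0339). It was lost for retinoic acid (0.169), PD0325901 (0.0724) and embryoid bodies (0.301). All share the CMAF arrays, so these are not independent. Pdk1, which limits the oxidation of pyruvate in mitochondria, fell by 2.47 with BMP4 and by 3.25 with PD0325901.

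Of the 32 arrays with neither morphogen nor compound, most had retinoic acid target levels (mean normalized log2 signal) between 8.16 and 8.36. EpiSC-5 replicate 10 and EpiSC-G replicate 9 had 9.36 and 9.10, and both were closest to retinoic acid arrays, but their Nodal and Activin target levels of 5.91 and 5.50 lay below all retinoic acid arrays of their line (lowest 6.51 and 6.14). EpiSC-5 replicates 2 and 8 and EpiSC-G replicate 8, closest to BMP4 arrays, had BMP target levels of 8.79, 9.09 and 8.74. Nodal and Activin target levels of both replicates 8 (5.64 and 5.60) lay below all BMP4 arrays of their line (lowest 6.40 and 6.56). EpiSC-5 replicate 4 was closest to an embryoid body array, EpiSC-5 replicate 3 and EpiSC-G replicates 4 and 5 to SB431542 arrays, and EpiSC-G replicate 11 to a CMAF array. Those closest to SB431542 had Nodal and Activin target levels of 6.38, 6.62 and 6.69, above all SB431542 arrays of their line and batch (highest 5.98, 5.73 and 5.93). EpiSC-5 replicates 16 and 17, closest to arrays of the same label, had retinoic acid target levels of 6.11 and 6.06. No array was moved to another group.

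Arrays of other conditions under this label may be present, though the Nodal and Activin target levels of several lie outside the range of the closest condition: 10 of the 32 were closest to an array of another condition, against 11 of 236 elsewhere. A single pooled RNA on most of these arrays is a candidate explanation for the rest. Over the 449 genes that differ between the lines in CMAF, the line difference on these arrays followed that in CMAF with a slope of 0.23 ± 0.02, against 0.43 to 0.71 in other conditions. No biological explanation was tested, since the labels do not give the medium.

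BIO-acetoxime raised Wnt targets by 2.48 in the factorial panel and 0.17 in the SB431542 panel at the same dose. Weaker responses to all compounds in the SB431542 panel are argued against by a median ratio of panel to factorial change of 1.26 over the targets of BMP4 (1.28), retinoic acid (0.733, a weaker response) and PD0325901 (1.26), against 0.0702 for BIO-acetoxime. A lack of response in EpiSC-G is argued against by an effect of 2.50 (95% interval 2.09 to 2.91, 5 arrays) in that line. Whether SB431542 may prevent the response cannot be told apart from other causes with 1 array: EpiSC-5 with SB431542 and BIO-acetoxime lay 3.21 above 11 other SB431542 arrays (8.74 against 5.53 ± 0.11).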
